A study of Mus musculus with 6 samples.

How the data were processed

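RNA sequencing of sorted intratumoral myeloid cells was analysed in 6 libraries, 2 for each of 3 populations, from CT26 tumours of 2 BALB/C mice. Groups were taken from the sample titles, and the mouse of each library from the source labels, so libraries of different populations were paired by animal. Per the labels, RNA was isolated with the RNeasy Micro kit and libraries were made by standard Illumina protocols. Whether the libraries were stranded is not stated.

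The deposited files gave 2 values per gene for the same 35275 genes in every library. The read counts were deposited by the authors as whole, unnormalized numbers per gene. The FPKM values were also made by the authors, as counts divided by gene length and by the library's own total, since count divided by FPKM gave the same gene length in every library (largest relative deviation 6.6e-12 over 21245 genes). Per the labels, TopHat, STAR 2.5 and HTSeq 0.6.1 were used with build mm10, without a role or an order for each, and the annotation release and filters are not stated. Only the counts were used for the comparisons. Coordinates and biotypes came from GENCODE M21, in which 34490 gene IDs matched and 785 did not, and 126 rows had a symbol shared with another row. Gene symbols were those of the files, so Adgre1 appears as Emr1 and the gene of VISTA as 4632428N05Rik.

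Total counts ran from 23595976 to 28045025 per library. A count of 0 was read as at most 3 counts of the library total. Reads had no molecular identifiers, so this limit covers counting error only.

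Before the data were examined, the comparisons, tests, 27 gene lists, the rule for named genes and most alternatives were fixed. Genes were kept by filterByExpr (13883 tested), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, R 4.3.3) on all 6 libraries, without a term for mouse, which left 3 residual degrees of freedom. The Benjamini-Hochberg adjustment was made over all tested genes of a comparison, with a threshold of 0.05. The 3 comparisons were T1-binding against T1-non-binding Ly6G-high cells, Ly6G-low against Ly6G-high T1-binding cells, and Ly6G-low T1-binding against Ly6G-high T1-non-binding cells. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over 81 tests. CPM values are scaled by TMM, given as mean ± SD of 2 libraries, and fold changes are those of the edgeR model with its standard error.

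As a check of the pairing, deviations from the group mean correlated at 0.51 across genes between the Ly6G-high populations of the same mouse, and at -0.04 and -0.01 between Ly6G-low and the Ly6G-high T1-non-binding and T1-binding populations. Models with mouse as a block left 2 residual degrees of freedom on 6 libraries and 1 on 4 libraries.

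Named genes were Ly6g, Itgam, Ptprc, Ly6c2 and Adgre1, whatever their result, and the 6 highest and 6 lowest fold changes among called genes with at least 10 CPM in the higher group and groups that did not overlap. From each list that was called or had 3 called members came the 2 called members with the smallest p and 1 of the other direction, and all called suppression-linked genes were added. Predicted genes, clone names, pseudogenes and antigen receptor segments were passed over. Between the Ly6G-high gates no gene was called, so the genes with the smallest p were named, and for lists the choice of the 2 members with the smallest p was made after the fits. The rule gave 41, 95 and 94 genes in the 3 comparisons, and the text names part of them, picked after their values were seen.

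Alternatives fixed beforehand were mouse as a block, the compared groups alone, RLE factors, DESeq2 1.42.0, limma-voom, no filter, at least 50 counts in 2 libraries, a 2-fold threshold and each library left out, and for lists an estimated correlation, fry and the block. Chosen after seeing the data were library totals, upper-quartile factors, DESeq2 with the block, the block on the 4 Ly6G-high libraries, leaving out libraries for the lists, the block with an estimated correlation, and settings for the library correlations. Genes shared by comparisons with the same T1-non-binding libraries were set beside independent lists and beside 50 simulations of unchanged groups. A leukocyte list of 22 genes was written after Ptprc and Itgam had been seen.

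The first comparison was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, without a mouse effect, with seed 11 kept after seeds 11 to 13 had been tried. With spread set by the trend, edgeR recovered 53 and 99, and 9 of 175 calls were false (5.14%). With gene-specific spread it recovered 44 and 100, and 25 of 182 calls were false (13.7%), more than the threshold allows. DESeq2 had 9.33% and 17.3% false calls, limma-voom 4.68% and 10.6%, and the block on 4 libraries 5.17% and 24.4%. In the fits a warning of zero variances appeared, and its origin was not traced.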

Results

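RNA was sequenced from myeloid cells sorted by flow cytometry out of subcutaneous CT26 tumours, a colon carcinoma line grown in BALB/C mice. The 3 sorted populations were each collected from the same 2 tumour-bearing mice, so that every population had 2 libraries and the libraries were paired by animal. The gates combined the neutrophil surface antigen Ly6G with binding of T1, an aptamer (a short folded nucleic acid that attaches to cells). They were Ly6G-low T1-binding cells, Ly6G-high T1-binding cells and Ly6G-high T1-non-binding cells. Which other markers were gated, and how pure the sorts were, is not stated. Tumours had reached 1800 mm^3. Counts in genes totalled 23595976 and 24956983 in the Ly6G-low libraries, 23673055 and 28045025 in the T1-non-binding libraries and 27821970 and 24183878 in the Ly6G-high T1-binding libraries (mouse 1, then mouse 2), and 13883 genes were abundant enough to be tested. A count of 0 in a library allows at most 0.107 to 0.127 CPM (counts scaled to library size in the usual unit) of its total, a limit that covers counting error only. Across genes, which are not independent replicates, log2 CPM of the 2 mice correlated at r = 0.986 in Ly6G-low cells, 0.975 in T1-non-binding cells and 0.981 in Ly6G-high T1-binding cells. The Ly6G-high gates of the same mouse correlated at r = 0.978 in mouse 1 and 0.977 in mouse 2, within the range of replicates. These pairs shared an animal, however, and replicates did not. Between different mice the Ly6G-high gates correlated at 0.960 and 0.974. Ly6G-low libraries correlated with Ly6G-high libraries at 0.839 to 0.918. Replicate counts differed by far more than sampling noise (chi-square per degree of freedom 24.98 to 98.7), and each library was counted as a separate sample. Between the Ly6G-high gates of the same mouse that value was 137 in mouse 1 and 125 in mouse 2.

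The genes for the sorting and lineage antigens were read first. Ly6g (ENSMUSG00000022582, chromosome 15, 75155240 to 75159126 on mm10) encodes the antigen of the gate. Its level was 0.106 ± 0.108 CPM in Ly6G-low cells, 31.5 ± 1.80 CPM in Ly6G-high T1-non-binding cells and 9.72 ± 0.470 CPM in Ly6G-high T1-binding cells (mean ± SD, n = 2 in each). Between the Ly6G-high gates Ly6g was 3.24-fold lower in the binding cells (log2 fold change -1.69 ± 0.27 SE, edgeR adjusted p = 0.385, not past the threshold of 0.05). Ptprc (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708), the common leukocyte antigen, was at 90.7 ± 35.1 CPM in Ly6G-low cells against 1245 ± 539 and 839 ± 256 CPM in T1-non-binding and T1-binding Ly6G-high cells. Itgam (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491), the integrin used to define myeloid cells, was at 284 ± 101, 1621 ± 717 and 1822 ± 528 CPM in the same order. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), a monocyte antigen, was at 19.6 ± 8.63, 113 ± 1.66 and 118 ± 26.3 CPM. Emr1 (ENSMUSG00000004730, chromosome 17, 57358691 to 57483527), now called Adgre1 and widely used as a macrophage marker, was at 91.5 ± 54.0, 183 ± 1.62 and 375 ± 51.5 CPM.

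**Figure D1:**
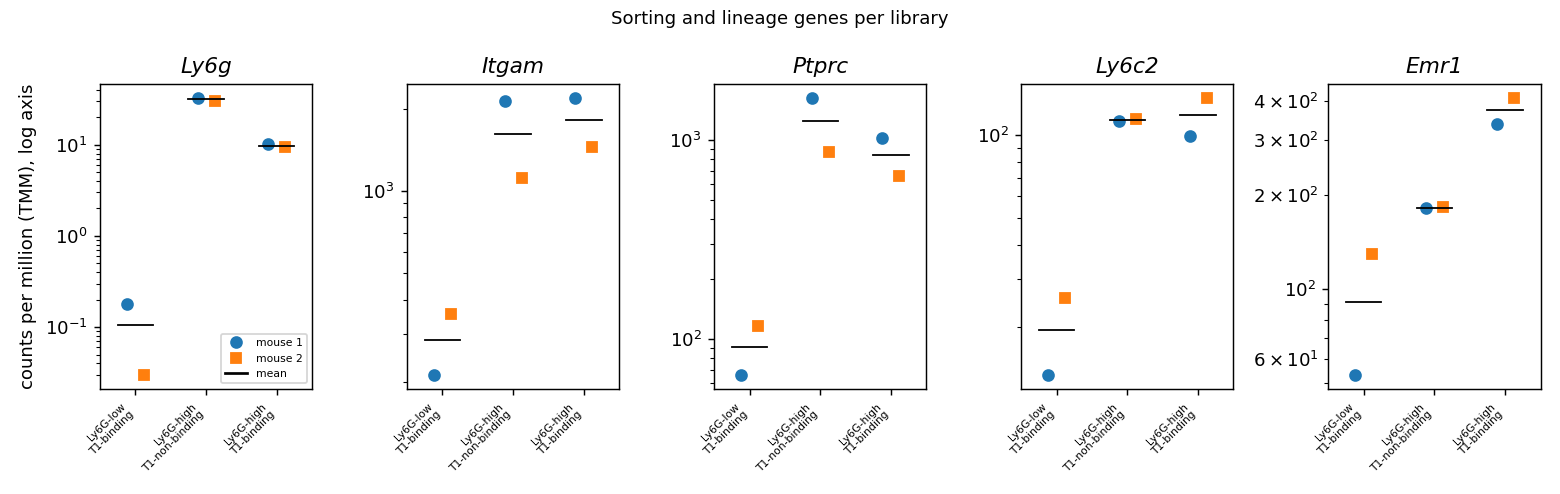
CPM (TMM-scaled, log axis) of Ly6g, Itgam, Ptprc, Ly6c2 and Emr1 in each of the 6 libraries, with mouse 1 as circles, mouse 2 as squares and the population mean as a black line. Ly6g lies at 0.106 CPM on average in Ly6G-low cells, 31.5 in Ly6G-high T1-non-binding cells and 9.72 in Ly6G-high T1-binding cells.

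The central comparison asked how Ly6G-high cells that bind the aptamer differ from Ly6G-high cells of the same tumours that do not. Macrophage genes were higher and neutrophil genes lower in the binding cells, as lists, while no single gene passed the threshold over all genes. Of 25 macrophage genes, 23 were higher, with a median log2 fold change of 1.05 (0.99 in mouse 1 and 1.09 in mouse 2). The list was higher by camera, a test of a list against the other genes, at adjusted p = 1.3e-18, and 14 members passed when adjusted over the list alone (0 over all genes). All 23 neutrophil identity genes were lower, with a median of -1.20 (camera adjusted p = 6.7e-17), and 4 passed when adjusted over the list alone (0 over all genes). With library totals in place of scaling factors, each of the 27 list medians of this comparison lay higher, by 0.14 to 0.31 (macrophage 1.31, neutrophil -0.91). With an estimated correlation between genes both list calls were lost (adjusted p = 0.515 with an estimated correlation for each). The other list test fixed beforehand, fry, called neither (fry adjusted p = 0.102 for macrophage and 0.163 for neutrophil genes). It called 0 of the 27 lists in this comparison.

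Among macrophage genes, Folr2, a folate receptor, was at 129 ± 28.6 against 57.1 ± 8.23 CPM, 2.26-fold higher. Ccl12, a monocyte-attracting chemokine, was 2.15-fold higher. The scavenger receptor list (median 0.88, 15 of 17 members higher, camera adjusted p = 1.6e-09, 4 higher over the list alone) included Stab1, at 389 ± 80.1 against 142 ± 34.5 CPM, and Mertk, a receptor for engulfing dying cells, which was 2.24-fold higher. Msr1, the class A scavenger receptor, was 2.18-fold higher (log2 fold change 1.13 ± 0.35 SE). Antigen presentation genes were higher as a list (median 0.55, 11 of 12 members higher, camera adjusted p = 7.4e-05), among them Cd40 (1.78-fold) and Ctss (1.88-fold). Smaller upward medians belonged to dendritic cell genes (0.22, camera adjusted p = 0.0459, with Irf8 1.68-fold higher), lipid uptake genes (0.32, adjusted p = 0.0134, with Lpl 1.63-fold higher) and mitochondrially encoded genes (0.38, adjusted p = 0.00498). The mitochondrial median was -0.05 in mouse 1 and 0.80 in mouse 2. With library totals the last 3 medians were 0.44, 0.58 and 0.68. With an estimated correlation these 5 calls were lost too (adjusted p = 0.515 for scavenger receptors and dendritic cell genes, 0.517 for antigen presentation, 0.582 for lipid uptake and 0.614 for mitochondrial genes).

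On the lower side, Retnlg, a neutrophil-secreted resistin-like protein, was at 229 ± 22.2 against 661 ± 107 CPM, 2.88-fold lower. The granule and precursor genes (median -1.38, 8 of 9 members lower, camera adjusted p = 7.1e-06, 4 lower over the list alone) included Ltf, or lactoferrin, at 24.4 ± 10.8 against 114 ± 35.0 CPM, and Lcn2, or lipocalin, 2.93-fold lower. Immediate-early and heat shock genes were lower in all 18 members (median -0.66, adjusted p = 4.5e-06), with Hspa1b 2.44-fold and Hspa1a 2.13-fold lower, and these near-identical neighbours could share reads. Glycolysis and hypoxia genes (median -0.61, adjusted p = 0.000135), led by the glucose transporter Slc2a3 (2.47-fold lower) and the lactate exporter Slc16a3 (2.05-fold lower), and endoplasmic reticulum stress genes (median -0.61, adjusted p = 0.000833), with Chac1 2.77-fold and Sesn2 2.15-fold lower, had negative medians too. Interferon-stimulated genes had a median of -0.34 (adjusted p = 0.0105), with Isg15 2.21-fold and Oasl1 1.85-fold lower. Markers of other cell types were lower too: the tumour and epithelial list had a median of -0.40 (adjusted p = 0.0454) and the fibroblast and endothelial list of -0.33 (adjusted p = 0.00338). In the latter, Emcn was at 0.0419 against 1.72 CPM, and Tek had no count in either binding library against 0.862 CPM. A count of 0 allows 0.108 and 0.124 CPM in those libraries, and the median is the same with Tek at that limit. Library totals brought the medians of this paragraph closer to 0: granule -1.09, immediate-early -0.37, hypoxia -0.31, stress -0.33, interferon-stimulated -0.07, tumour -0.17 and fibroblast -0.10. With an estimated correlation none of these calls held (adjusted p = 0.515 for granule genes, tumour and fibroblast markers, 0.562 for immediate-early, 0.619 for hypoxia and for interferon-stimulated and 0.517 for stress genes).

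Of the 14 lists called in this comparison, 6 were called without each of the 6 libraries in turn (neutrophil identity, macrophage, scavenger receptor, antigen presentation, immediate-early and stress genes), and 8 lost the call without at least 1 library. Granule genes lost it without Ly6G-high T1-binding replicate 2 (adjusted p = 0.497, with the test pointing up). Hypoxia (adjusted p = 0.529 and 0.117) and interferon-stimulated genes (adjusted p = 0.377 and 0.0988) lost it without T1-non-binding replicate 1 and without Ly6G-high T1-binding replicate 2. Lipid uptake genes (adjusted p = 0.314 and 0.265) and fibroblast markers (adjusted p = 0.261 and 0.230) lost it without T1-non-binding replicate 2 and without Ly6G-high T1-binding replicate 1. Mitochondrial genes lost it without replicate 2 of the non-binding (adjusted p = 0.0789) or the binding cells (adjusted p = 0.258). Dendritic cell genes lost it without either non-binding library (adjusted p = 0.0766 and 0.0903) or binding replicate 1 (adjusted p = 0.249). Tumour markers lost it without any library other than Ly6G-low replicate 1 (adjusted p = 0.0537 to 0.314). These fits had no term for mouse, so leaving out a library of either Ly6G-high gate also unbalanced the mice. Within mouse 1 and mouse 2, 7 of these 8 lists had medians of one sign: granule -1.36 and -1.41, hypoxia -0.75 and -0.31, interferon-stimulated -0.47 and -0.24, lipid uptake 0.20 and 0.32, fibroblast -0.45 and -0.26, dendritic cell 0.20 and 0.13, and tumour -0.41 and -0.47. The mitochondrial medians differed in sign. With mouse as a block over all 6 libraries the 14 lists were still called (granule adjusted p = 6.8e-10). With that block and an estimated correlation none was called by camera (adjusted p = 0.289 for granule, 0.165 for neutrophil identity and 0.602 for macrophage genes). Of the lists not called, 12 were called without at least 1 library. Adjusted over the list alone, 1 antigen presentation gene and 1 lysosomal gene passed as higher, 1 interferon-stimulated and 2 fibroblast or endothelial genes as lower, and the stress list had 1 higher and 4 lower, against 0 in each over all genes.

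**Figure D2:**
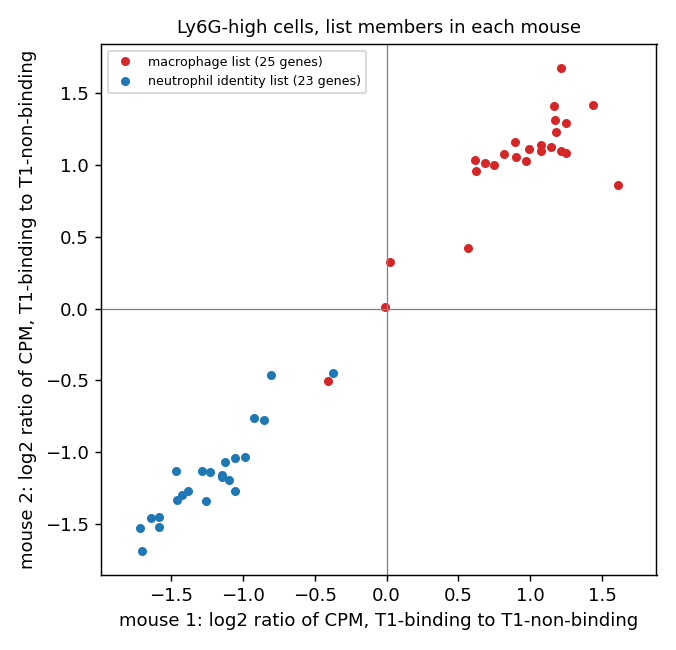
Each point is a gene of the macrophage list (25 genes, red) or the neutrophil identity list (23 genes, blue), and both axes give the log2 ratio of CPM in T1-binding to T1-non-binding Ly6G-high cells, for mouse 1 on the horizontal and mouse 2 on the vertical axis. The macrophage median was 0.99 in mouse 1 and 1.09 in mouse 2, and the neutrophil median was -1.23 and -1.17.

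The list of genes tied to suppression by myeloid cells was not called (24 members, 8 higher, median -0.33, and -0.04 with library totals, camera adjusted p = 0.185). It was lower at adjusted p = 0.000372 without T1-non-binding replicate 2 and at adjusted p = 0.0024 without Ly6G-high T1-binding replicate 1. Nor were 12 further lists called. Their medians were 0.03 for monocyte genes, 0.06 for the phagocyte oxidase, 0.01 for inflammatory cytokines, 0.14 for endocytosis and lysosome, -0.06 for Fc and complement receptors and -0.09 for matrix remodelling. They were -0.21 for cell cycle, -0.06 for ribosomal proteins, 0.22 for T and NK cells, 0.25 for eosinophil, mast and basophil genes and -0.37 for erythroid and platelet genes, and about -1 for B cell genes, the furthest from 0 of the 13 lists not called (-0.24 in mouse 1 and -1.47 in mouse 2). With library totals in place of scaling factors, the cytokine median was 0.32, the Fc receptor median 0.24, the matrix median 0.18, the cell cycle median 0.03 and the ribosomal median 0.17. The sign of 4 of these 5 was therefore set by the scaling, and RLE factors turned the fifth (-0.01 for cytokines). For 3 lists the measures disagreed in sign: camera pointed up for Fc receptors (mean -0.01), matrix remodelling (mean 0.05) and erythroid genes (mean -0.09) although their medians were negative.

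Across the 13883 genes, 0 were called at an adjusted p below 0.05 by edgeR's quasi-likelihood test (smallest adjusted p = 0.385). At an unadjusted p below 0.05 there were 742 higher and 881 lower genes, where 694 in all are expected by chance. The genes with the smallest p, none past the threshold, included Pglyrp1 (3.08-fold lower), N4bp3 (1.93-fold lower) and Tbc1d10c (2.58-fold lower), and on the higher side Scamp5 (2.08-fold), Tmem37 (2.24-fold), Tmem206 (2.04-fold), Kcnk13 (2.45-fold), Plxdc1 (2.21-fold) and Ptgr1 (2.08-fold). Limma-voom also called 0, and DESeq2 called 203 (69 higher and 134 lower). With mouse as a block over all 6 libraries edgeR called 0 (smallest adjusted p = 0.0570), but the neutrophil genes past the threshold over the list alone went from 4 to 23. That block assumes the same mouse shift in every population. Mouse deviations were shared by the Ly6G-high gates (correlation 0.51) but not with Ly6G-low cells (-0.04 and -0.01). This 0 therefore does not settle what pairing gains. A block fitted to the 4 Ly6G-high libraries alone, chosen after the 0 had been seen, called 3778 of 13419 genes (1823 higher and 1955 lower), including 22 of 25 macrophage genes higher, 1 lower, and 23 of 23 neutrophil genes lower. That fit has 1 residual degree of freedom of its own and takes the rest from all genes (median prior degrees of freedom 33.3). In simulated data 24.4% of its calls were false with gene-specific spread (5.17% with spread set by the trend). The simulated data had no mouse effect, so they do not measure what pairing gains. Nor do they give the share of false calls among these 3778.

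The comparison of T1-binding cells across the Ly6G gate showed lower myeloid transcripts of nearly every kind in Ly6G-low cells. All 23 neutrophil identity genes fell, with a median log2 fold change of -5.63 (camera adjusted p = 5.8e-30), and Ly6g itself was 89.5-fold lower. Macrophage genes fell as well: 22 of 25 were called lower and 2 higher (median -2.02, adjusted p = 9.9e-09). Monocyte genes (14 of 16 lower, median -2.35), antigen presentation genes (11 of 12 lower, median -2.28) and inflammatory cytokines (22 of 23 lower, median -2.65) were called as well, with camera adjusted p between 4.5e-11 and 1.7e-08. With an estimated correlation all 5 list calls were lost (adjusted p = 0.515 for each). This setting estimated a correlation of 0.88 for the neutrophil genes and missed them, although 23 of 23 were called singly. It called 0 of 81 lists, so losses under it cannot tell lists apart. Fry called 13 of the 27 lists in this comparison, neutrophil genes among them (fry adjusted p = 0.0311). Ptprc was 9.26-fold lower (log2 fold change -3.21 ± 0.47 SE, edgeR adjusted p = 0.00394), Itgam 6.42-fold, Ly6c2 6.03-fold and Emr1 4.10-fold lower. Cell cycle genes rose, with 19 of 22 called higher (median 0.97, camera adjusted p = 2.2e-06, and adjusted p = 0.522 with an estimated correlation).

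The suppression-linked list fell (20 members called lower, 2 higher and 2 not called, median -2.53, camera adjusted p = 9.9e-09, adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 21 were lower and 2 higher. For scale, 22 of 22 leukocyte genes, a list written after Ptprc and Itgam had been seen, were called lower too, with a median of -2.67. Arg1, the arginine-degrading enzyme, was at 220 ± 3.65 CPM in Ly6G-low cells against 1166 ± 551 CPM in Ly6G-high cells (5.31-fold lower, edgeR adjusted p = 0.00985), and its paralogue Arg2 was 10.9-fold lower. The calls of Arg1, Itgam, Nos2, Ptges, Stat3, Vegfa and Tnfrsf10b were lost without Ly6G-low replicate 1, at log2 fold changes of -2.43, -2.36, -2.40, 1.16, -1.58, -1.72 and 1.28. Without Ly6G-high T1-binding replicate 1 those of Nos2 (-1.85), Stat3 (-1.36), Vegfa (-1.30) and Tnfrsf10b (0.97) were lost, and without Ly6G-low replicate 2 those of Vegfa (-1.84) and Tnfrsf10b (0.88). Nos2, the inducible nitric oxide synthase, was at 7.56 ± 1.20 against 44.4 ± 24.3 CPM. Checkpoint ligands and receptors included Cd274 (10.7-fold lower), Pdcd1lg2 (5.72-fold), Havcr2 (5.88-fold), Lgals9 (3.34-fold) and 4632428N05Rik, the gene of the checkpoint protein VISTA (5.90-fold). The adenosine-producing ectoenzymes Entpd1 and Nt5e were 16.9-fold and 6.76-fold lower. The cytokines and receptors Il10 (4.48-fold), Tgfb1 (3.88-fold), Il4ra (4.79-fold), Il1rn (13.7-fold) and Vegfa (3.33-fold) were lower, as were the transcription factors Cebpb (8.39-fold) and Stat3 (3.11-fold). Olr1 (7.58-fold), Cd84 (6.59-fold) and Wfdc17 (7.41-fold) completed the lower set. Ptges, a prostaglandin E synthase, rose 2.35-fold to 180 ± 12.4 CPM, and Tnfrsf10b, a death receptor, rose 2.19-fold.

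Among called genes with at least 10 CPM in the higher population, no overlap between the populations and a symbol within the naming rule, the largest falls were those of Mrgpra2a, Ankrd22, Olfm4, Stfa2, Mrgpra2b and Chil1. Olfm4, a neutrophil granule protein, was at 0.571 ± 0.439 against 80.5 ± 40.0 CPM, and Chil1 at 0.587 ± 0.544 against 69.2 ± 23.5 CPM. Mrgpra2a and Mrgpra2b are near-identical receptors whose reads could be split between them. The largest rises under the same limits were Gpr124 (4.87-fold), an adhesion receptor of vessels and stroma, Npm3 (4.19-fold), Lgals7 (4.09-fold), an epithelial galectin, Hmga2 (4.05-fold), a chromatin protein of embryonic and tumour cells, Nppb (3.93-fold) and the matrix glycoprotein Tnc (3.88-fold, not called without Ly6G-low replicate 1, at 2.14, or 2, at 1.66). Hmga2 stood at 138 ± 14.9 against 34.1 ± 7.75 CPM. Over all tested genes, 612 were called at least 8-fold lower and 24 at least 8-fold higher. Over 4038 genes with 50 CPM or more in both Ly6G-low libraries, few could rise so far. Percentile 1 of their level in the T1-binding Ly6G-high libraries was 16.5% and 26.3% of the Ly6G-low level (library totals). Whether mixed RNA sets this limit stays open, so these counts need not reflect the cells alone.

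Markers of other cell types did not move together. In the fibroblast and endothelial list (median 1.03, camera adjusted p = 0.133, not called) 7 genes rose, among them Sparc at 359 ± 73.8 against 118 ± 34.6 CPM, and 3 fell, among them Acta2 (16.0-fold) and Pecam1 (7.17-fold), the latter also carried by leukocytes. In the tumour and epithelial list (median 0.32, adjusted p = 0.400, not called) 3 members were called higher, among them Ereg (2.72-fold), and 1 lower. T and NK genes fell (11 of 18 lower, median -1.42, adjusted p = 0.00102), with Cd3d at 0.342 against 4.51 CPM and Cd2 at 1.74 against 5.13 CPM. Erythroid and platelet genes fell (6 lower, 1 higher, median -2.29, adjusted p = 0.0357), with Hba-a1 at 4.30 against 24.3 CPM, its twin copy Hba-a2 at 1.03 against 4.72 CPM, and Itga2b rising to 1.87 from 0.394 CPM. With an estimated correlation the last pair of list calls was lost (adjusted p = 0.562 and 0.620). Without Ly6G-low replicate 1 the calls of Sparc (1.37), Cd2 (-1.22), Hba-a1 (-2.39), Hba-a2 (-1.92) and Itga2b (1.99) were lost, and without Ly6G-high T1-binding replicate 1 those of Sparc (1.33) and Itga2b (2.17). B cell genes (median 0.13, mean -0.33, camera pointing down at adjusted p = 0.631) and eosinophil, mast and basophil genes (median -1.65, adjusted p = 0.0765, with Ear2 5.84-fold and Siglec5 14.8-fold lower and Gata2 2.84-fold higher) were not called.

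The remaining myeloid lists fell. They were granule genes (9 of 9, median -3.56, camera adjusted p = 1.9e-07), dendritic cell genes (13 lower with Irf8 4.14-fold, 1 higher, Fscn1 at 2.12-fold, median -1.90, adjusted p = 0.000315), the phagocyte oxidase (9 of 10, median -1.93, adjusted p = 5.4e-06), interferon-stimulated genes (23 of 24 lower, median -1.65, adjusted p = 2.8e-12) and Fc and complement receptors (15 of 16, median -2.69, adjusted p = 4.9e-10). Isg15, an antiviral ubiquitin-like protein, was at 27.4 ± 1.09 against 299 ± 37.8 CPM. These 5 calls were lost with an estimated correlation (adjusted p = 0.515 for each). Scavenger receptors (14 of 17, median -2.08, adjusted p = 1.2e-06), lysosomal genes (20 lower, 1 higher, median -1.40, adjusted p = 3.3e-06), lipid uptake (13 lower, 2 higher, median -1.60, adjusted p = 0.000632) and matrix remodelling (13 lower, 2 higher, median -1.78, adjusted p = 0.00102) fell on balance. These 4 list calls were lost with an estimated correlation (adjusted p = 0.515, 0.522, 0.515 and 0.562). Cav1, a caveolar protein (2.73-fold), Scd1, a fatty acid desaturase (2.68-fold), and Timp1, a metalloproteinase inhibitor (3.20-fold), rose within them. Without Ly6G-low replicate 1 the calls of Cav1 (1.29), Timp1 (1.46) and Fscn1 (1.06) were lost, without Ly6G-low replicate 2 that of Fscn1 (1.03), and without Ly6G-high T1-binding replicate 1 those of Timp1 (1.45) and Fscn1 (0.98). Immediate-early genes (13 of 18, median -1.95, adjusted p = 1.4e-05) and hypoxia genes (8 of 25 lower and 17 not called, median -0.76, and -0.16 with library totals, adjusted p = 0.000955, with Slc2a3 59.7-fold lower) fell (adjusted p = 0.562 and 0.638 with an estimated correlation). Ribosomal protein genes were higher as a list (median 0.80, 3 of 30 called, adjusted p = 6.4e-05, adjusted p = 0.619 with an estimated correlation). Mitochondrial genes (median 0.40, adjusted p = 0.0937) and stress genes (median -0.03, and 0.56 under library totals, adjusted p = 0.418) were not called.

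Of the 21 lists called between the T1-binding gates, 20 were called without each library in turn, and erythroid genes lost the call without Ly6G-low replicate 2 (adjusted p = 0.115) or Ly6G-high T1-binding replicate 1 (adjusted p = 0.0786). Fibroblast and endothelial markers were called higher without replicate 2 of the Ly6G-low (adjusted p = 0.0387) or the Ly6G-high T1-binding cells (adjusted p = 0.0460), as were mitochondrial genes (adjusted p = 0.0265 and 0.0154). B cell genes were called without Ly6G-low replicate 2 (adjusted p = 0.0457) and eosinophil genes without Ly6G-low replicate 1 (adjusted p = 0.000214). Adjusted over the list alone, the counts differed from those over all genes in 13 lists. Lower members were then 23 for macrophage, 10 for phagocyte oxidase, 14 for lipid uptake, 15 for scavenger, 6 for stress, 14 for immediate-early, 13 for T and NK, 1 for B cell and 8 for erythroid genes, next to the 21 suppression-linked genes. Cell cycle genes then had 20 higher, ribosomal protein genes 0, and tumour markers 4 higher and 2 lower.

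In all, edgeR called 5971 genes, 2604 higher and 3367 lower in Ly6G-low cells. The Ly6G-low libraries had TMM scaling factors of 1.40 and 1.39, against 0.858 and 1.00 in Ly6G-high T1-binding libraries. Without scaling factors the 27 list medians lay 0.54 to 0.62 higher (tumour 0.86, fibroblast 1.58, lysosomal -0.82, T and NK -0.87), the median gene lay at 0.61 in place of 0.03 on the log2 scale and the split became 5208 higher and 2235 lower, and with upper-quartile factors it was 3588 and 3096. Counts fell without Ly6G-low replicate 1 (1972 genes), without Ly6G-low replicate 2 (3105) and without Ly6G-high T1-binding replicate 1 (2512). Transcripts of Lars2 made up 0.0761% and 0.0888% of counts in Ly6G-low libraries and 1.02% and 1.81% in Ly6G-high T1-binding libraries, and mitochondrial transcripts 1.21% and 0.958% against 0.395% and 0.626%.

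**Figure D3:**
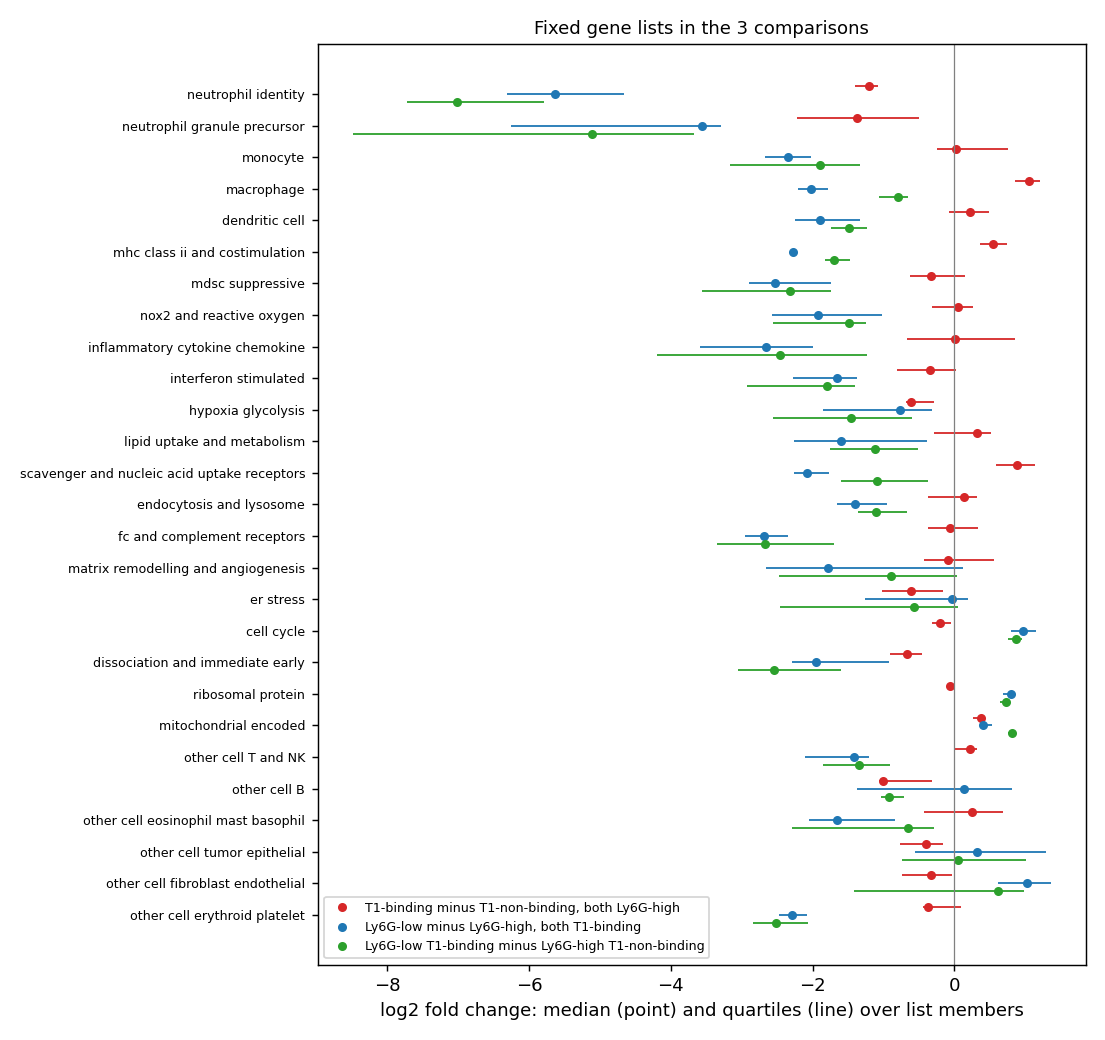
Median log2 fold change (point) and quartiles (line) over the tested members of each of the 27 gene lists fixed before the data were examined, for the 3 comparisons in 3 colours. The neutrophil identity median is -1.20 between the Ly6G-high gates (red), -5.63 between T1-binding gates (blue) and -7.01 between Ly6G-low T1-binding and Ly6G-high T1-non-binding cells (green).

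The third comparison, of Ly6G-low T1-binding with Ly6G-high T1-non-binding cells, crossed both gates. Neutrophil genes were again the most strongly lowered (23 of 23, median -7.01, camera adjusted p = 9.5e-39), with Ly6g 290-fold lower, and granule genes followed (9 of 9, median -5.12, adjusted p = 1.3e-09, with Lcn2 34.7-fold lower). The size of the Ly6g fall is uncertain here too, for the same reason. Both list calls were lost with an estimated correlation (adjusted p = 0.515 for each). Macrophage genes fell less here: 8 of 25 were called lower and 1 higher (median -0.80, adjusted p = 0.0148, adjusted p = 0.620 with an estimated correlation), and without scaling factors their median was -0.0022. The call was lost without Ly6G-low replicate 1 (adjusted p = 0.0893) or T1-non-binding replicate 2 (adjusted p = 0.0872). Cd68, a lysosomal protein of macrophages and other phagocytes, was 4.39-fold lower and Fcgr1 2.95-fold lower, while Axl, a receptor for dying cells, rose 1.94-fold to 1334 ± 53.3 CPM. Emr1, at 2.00-fold lower, did not pass (adjusted p = 0.0801). Ptprc was 13.7-fold lower (adjusted p = 0.00241), Itgam 5.71-fold and Ly6c2 5.79-fold lower. Without Ly6G-low replicate 1 the calls of Cd68 (log2 fold change -1.86), Fcgr1 (-1.17), Itgam (-2.19) and Axl (0.91) were lost, and that of Axl also without Ly6G-low replicate 2 (0.96) and T1-non-binding replicate 1 (0.80), while Emr1 was called without Ly6G-low replicate 2 (-1.81).

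Suppression-linked genes fell (21 lower, 1 higher and 2 not called of 24, median -2.32, camera adjusted p = 2.0e-09, adjusted p = 0.515 with an estimated correlation), and the 22 leukocyte genes fell too (22 called lower, median -2.88). Entpd1 was 33.7-fold, Il1rn 24.9-fold, Cd274 21.2-fold, Arg2 18.2-fold, Cebpb 15.9-fold and Wfdc17 15.3-fold lower. Arg1 was 2.74-fold lower (220 ± 3.65 against 601 ± 325 CPM, adjusted p = 0.0481), Ptgs2, the inducible cyclooxygenase, 3.50-fold lower and Nos2 5.25-fold lower. The other 12 lower members lay between Olr1 (10.8-fold) and Il10 (2.17-fold), and Ptges rose 1.87-fold. The calls of Arg1, Nos2, Ptgs2, Ptges, Vegfa and Nt5e were lost without either Ly6G-low library and without T1-non-binding replicate 1, where (for the last) their log2 fold changes were -0.76, -1.44, -0.99, 0.70, -0.92 and -1.44. Those of Stat3 (-1.94), Tgfb1 (-1.83) and Il10 (-0.94) were lost without Ly6G-low replicate 1. Adjusted over the list alone, 21 members were lower and 2 higher. Under the limits given above, the deepest falls were Amer2, without a count in either Ly6G-low library against 10.4 ± 1.08 CPM, Camp (0.0304 against 17.4 CPM), Ankrd22 (0.0760 against 38.0 CPM), Olfm4 (0.571 against 209 CPM), Ltf (0.316 against 114 CPM) and Mrgpra2a (0.104 against 35.3 CPM). The largest rises under the same limits were smaller: Unc13c (2.94-fold), Mum1l1 (2.86-fold), Kif20b (2.82-fold) and Cenpf (2.75-fold), which act in mitosis, Gcnt4 (2.82-fold) and Plxna2 (2.81-fold). Unc13c was not called without Ly6G-low replicate 1 (1.56) or 2 (1.51) or T1-non-binding replicate 1 (1.30). Over all tested genes, 884 were called at least 8-fold lower and 5 at least 8-fold higher. The reservation on such counts given above holds here too, with percentile 1 at 16.5% and 32.4% in the T1-non-binding libraries.

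Other lists fell as in the preceding comparison. Their medians were -1.90 for monocyte genes, -1.49 for dendritic cell genes, -1.70 for antigen presentation, -1.49 for the phagocyte oxidase, -2.46 for cytokines, -1.80 for interferon-stimulated genes and -2.67 for Fc and complement receptors (camera adjusted p between 1.0e-14 and 0.00448, and adjusted p = 0.515 with an estimated correlation for each). Immediate-early genes (-2.55), hypoxia genes (-1.45), lysosomal genes (-1.10), lipid uptake (-1.12), scavenger receptors (-1.09), matrix remodelling (-0.90), T and NK genes (-1.34) and erythroid genes (-2.52) were lower as lists. With library totals each of the 27 medians of this comparison lay higher, by 0.72 to 0.94. Those of hypoxia (-0.55), lysosomal (-0.21), lipid uptake (-0.22), scavenger receptor (-0.20), matrix (-0.03), T and NK (-0.55), phagocyte oxidase (-0.63), dendritic cell (-0.64), antigen presentation (-0.87), monocyte (-1.01) and interferon-stimulated genes (-0.92) then lay closer to 0. The largest camera adjusted p among these 8 was 0.0459, and adjusted p = 0.517 to 0.643 with an estimated correlation ended the calls. Stress genes were called lower (median -0.57, adjusted p = 0.0427, adjusted p = 0.619 with an estimated correlation), but without scaling factors the median was 0.31. Cell cycle genes rose (15 of 22, median 0.88, adjusted p = 8.0e-05, with Ccnb1 1.98-fold and Bub1 1.92-fold higher). Neither was called without Ly6G-low replicate 1 (both 0.91) or 2 (1.03 and 0.93), nor Ccnb1 without T1-non-binding replicate 1 (0.88). Mitochondrial genes (3 of 11 called, median 0.82, adjusted p = 0.00534) and ribosomal protein genes (0 of 30 called, median 0.73, adjusted p = 0.000135) were higher as lists. With an estimated correlation, adjusted p = 0.562, 0.614 and 0.620 for these 3. B cell genes (median -0.93, and -0.21 without scaling factors), eosinophil, mast and basophil genes (-0.65, and 0.22 without scaling factors), tumour markers (0.06, -0.01 with RLE factors and 0.92 without factors) and fibroblast markers (0.62, and 1.38 without factors) were not called. The means of the last pair were -0.30 and -0.30, opposite in sign to their medians and to camera.

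Of the 23 lists called in the third comparison, 19 were called without each library in turn. Beside macrophage genes, stress genes lost the call without Ly6G-low replicate 2 (adjusted p = 0.0968), T and NK genes without T1-non-binding replicate 2 (adjusted p = 0.175), and erythroid genes without Ly6G-low replicate 2 (adjusted p = 0.132), T1-non-binding replicate 1 (adjusted p = 0.266) or Ly6G-high T1-binding replicate 1 (adjusted p = 0.0582). B cell genes were called lower without Ly6G-low replicate 2 (adjusted p = 0.00652) and eosinophil genes without Ly6G-low replicate 1 (adjusted p = 0.00158). Adjusted over the list alone, cell cycle genes had 19 higher and 1 lower, mitochondrial genes 6 higher, cytokines 20 lower, lysosomal genes 18 lower, dendritic cell genes 11 lower, matrix genes 2 higher, fibroblast markers 5 higher, suppression-linked genes 2 higher (as above) and B cell genes 0, and counts in the other lists were those over all genes.

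Here edgeR called 5528 genes, 2230 higher and 3298 lower. The split was 7262 higher and 1883 lower without scaling factors, where the median gene lay at 0.91 in place of 0.09, and 3786 and 3002 with upper-quartile factors. Counts were 1527 without Ly6G-low replicate 1, 2418 without Ly6G-low replicate 2 and 2369 without T1-non-binding replicate 1. Lars2 made up 1.12% and 1.35% of counts in T1-non-binding libraries.

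Genes that set both T1-binding populations apart from the shared T1-non-binding libraries were then counted. Since no gene was called between the Ly6G-high gates, 0 genes were called in both, and 0.1 on average (at most 2) in 50 simulations of unchanged groups. DESeq2 placed 119 genes in both. At an unadjusted p below 0.05, 73 genes were higher in both, fewer than the 185 of independent lists and the 89.9 of the simulations, and 594 were lower in both, against 244 and 59.8. The covariance of the fold changes was 0.332, against 0.0827 in the simulations. With only 2 control libraries these could not be split, and part of the excess may come from sharing them. In the simulations neither binding population differed from the controls. The real Ly6G-low cells had 3456 higher and 3845 lower genes at an unadjusted p below 0.05 by edgeR. The simulations therefore do not show what shared controls give when a population differs, and no conclusion is drawn from them. The fits also had no mouse term.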

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

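Library totals, upper-quartile factors, DESeq2 with mouse as a block, the block on the 4 Ly6G-high libraries, the left-out libraries for lists, the block with an estimated correlation and the settings for library correlations were chosen after seeing the data; the other alternatives were planned. Between the Ly6G-high gates, edgeR called 0 (742 higher and 881 lower at an unadjusted p below 0.05). Of the 12 alternatives other than left-out libraries, no filter gave 71 genes, DESeq2 203 and DESeq2 with the block 564. The block on the 4 Ly6G-high libraries gave 3778, and the rest gave 0. The cause of these differences was not tested. From 0 genes the 2-fold threshold can only give 0, so it adds no support. Fits with a library left out have less power than a test that already called 0, and are not counted here. Ly6G-low against Ly6G-high T1-binding cells gave 5971 genes, within 1.5 times under 14 of 17 alternatives, and 1972 to 6731 with a library left out. The third comparison gave 5528, with 3462 at a 2-fold threshold, which by construction can only lower it, 9145 with library totals, and 1527 to 6282 with a library left out. With 1 library left in a group, it is assumed to vary like the other groups. Genes in both T1-binding populations numbered 0, and 36 without a filter, 119 by DESeq2 and 403 by DESeq2 with the block. Of 81 list tests 58 were called, 54 to 62 with a library left out, 22 by fry, 0 with an estimated correlation and 0 with the block and an estimated correlation. The block on all 6 libraries changed no list call and moved no count of genes called over all genes by over 1.5 times, but lower genes at an unadjusted p below 0.05 between the Ly6G-high gates went from 881 to 1346, and several counts over the list alone rose by over 1.5 times. Between the Ly6G-high gates these were neutrophil (4 to 23 lower), interferon-stimulated (1 to 5 lower), scavenger (4 to 9 higher) and lysosomal genes (1 to 3 higher, 0 to 1 lower), and from 0 cytokines (6 higher, 4 lower), matrix (4 higher, 1 lower), monocyte (1 higher, 2 lower), suppression-linked (1 higher, 1 lower), hypoxia (2 lower), immediate-early (3 lower), T and NK (1 lower), tumour (1 lower) and erythroid genes (2 higher). Between the T1-binding gates they were ribosomal (0 to 26 higher), fibroblast (7 to 11 higher), hypoxia (8 to 14 lower) and B cell genes (1 to 3 lower), and in the third comparison ribosomal (0 to 27 higher), macrophage (8 to 18 lower), T and NK (7 to 13 lower), erythroid (5 to 8 lower) and B cell genes (0 to 4 lower). Granule genes between the Ly6G-high gates reversed without Ly6G-high T1-binding replicate 2 (adjusted p = 0.497, range over left-out libraries 5.7e-06 to 0.497), in a fit without a mouse term, while their medians within the mice were -1.36 and -1.41. Ribosomal genes, not called, pointed up without T1-non-binding replicate 2 (adjusted p = 0.0213) or Ly6G-high T1-binding replicate 1 (adjusted p = 0.00787), and down without their partners (range 0.000448 to 0.826). Ribosomal protein genes made up 1.2% and 1.4% of counts in the Ly6G-high libraries of mouse 1, and 2.2% and 2.4% in those of mouse 2. In each of these fits, without a mouse term, mouse 2 weighed more in the gate that pointed higher. The cause of the granule reversal was not tested. The lowest within-group library correlation was 0.975, and 0.982 without a filter. Of 1615 values for the 95 genes named between T1-binding gates 1569 kept direction and side of the threshold and 46 lost the call; of 1598 for the 94 of the third comparison 1488 kept both, 92 lost the call and 18 gained it; of 734 for the 41 between the Ly6G-high gates 622 kept both, 109 gained a call and 3, not called either way, changed sign with a library left out (Itgam in 2 settings, -0.22 and -0.16, and Ly6c2 in 1, -0.14). Depth limits genes below about 0.127 CPM.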

Other observations

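All tests in this part were chosen after the results they measure had been seen. With mouse as a block on the 4 Ly6G-high libraries alone, 263 called genes were at least 2-fold higher and 411 at least 2-fold lower in T1-binding cells, on 1 residual degree of freedom. Among those with 10 CPM or more in both libraries of a group, picked after their values were seen, the largest folds upward were those of Slco2b1 (3.11-fold), Col14a1 (2.87-fold), Stab1 (2.85-fold), Cx3cr1 (2.84-fold), Mmp13 (2.83-fold) and the mannose receptor Mrc1 (2.79-fold). The largest downward were those of the granule genes Ngp (5.59-fold) and Ltf (4.60-fold), of Ly6g (3.12-fold) and of Cldn1 (3.02-fold). In this fit 13 scavenger receptor genes were higher and 1 lower, 17 of 25 hypoxia genes and 14 of 18 immediate-early genes were lower, and suppression-linked genes went both ways, 5 higher and 10 lower of 23. The fibroblast and endothelial list had 0 higher and 7 lower of 15.

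Transcripts shared by leukocytes were low in the Ly6G-low libraries, although the labels call the sorted cells myeloid: of 22 leukocyte genes, 1 of them also in the phagocyte oxidase list and 1 in the Fc receptor list, 22 were called lower against each Ly6G-high population and 0 were called between the Ly6G-high gates. The 3 most abundant there were Lcp1, at 427 and 630 CPM (mouse 1, mouse 2) against 2501 and 1992 CPM in T1-non-binding cells, Laptm5, at 379 and 608 against 1372 and 1256 CPM, and Arhgdib, at 412 and 459 against 488 and 553 CPM (library totals). Scaling factors are argued against, since with library totals the medians were -2.08 and -1.98. None of the macrophage, monocyte and dendritic cell lists had a positive median against either Ly6G-high population. With library totals the lower of a list's medians was at most -1.31, though that of macrophage genes against T1-non-binding cells was -0.0022. The Ly6G-high libraries were themselves sorted as myeloid cells and held macrophage transcripts (Mrc1 at 202 to 780 CPM). These medians therefore cannot decide whether the Ly6G-low libraries are mainly macrophages, monocytes or dendritic cells. It also stays open that most of this RNA may come from cells that are not leukocytes, such as tumour or stromal cells. Of the tumour, fibroblast and endothelial lists, 16 markers had 10 CPM or more in both Ly6G-low libraries, and the rest did not. Among the 16, Col1a2 was at 1101, Sparc at 499 and Krt8 at 117 CPM (mean, library totals). Ptprc was at 91.8 and 160 CPM there. These levels do not give the share of such cells. The highest median of the leukocyte genes was -1.98 over both comparisons and scalings. A gate on Ptprc or Itgam protein would remove such cells if one was used (the labels do not say). Leukocytes with less of these transcripts were not tested.

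Genes abundant in the Ly6G-low libraries were also found in the Ly6G-high libraries: over 4038 genes with 50 CPM or more there (library totals), percentile 1 of the ratio of levels was 16.5% to 32.4% in the 4 Ly6G-high libraries. Over 16 tumour and fibroblast markers the median ratio to the Ly6G-low level was 20.3% and 43.7% in the T1-non-binding and 21.7% and 43.6% in the T1-binding libraries of mouse 1 and mouse 2. Single markers ran from 9.23% to 204%. Cd44 was the highest in each library (123% to 204%), so not every marker was particular to Ly6G-low cells. Reads exchanged between libraries are argued against, since neutrophil genes stood in the Ly6G-low libraries at 1.88% of their Ly6G-high level, against 32.7% for the markers the other way. Cells or RNA of the Ly6G-low kind mixed into the Ly6G-high libraries could give such a common ratio, but the median was up to 2.35 times the lowest ratio, where the bound set for the test was 2, so it stays open. Only Ly6G-high T1-binding replicate 1 passed that bound, through Lgals7 at 9.23%, and the other libraries lay at 1.37 to 1.78. Over the 4038 genes percentile 5 was 19.3% to 37.3%, not far above percentile 1. Expression of these genes by the Ly6G-high cells was not tested.

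Macrophage genes were higher and neutrophil genes lower in T1-binding than in T1-non-binding Ly6G-high cells of both mice. A mere shortage of neutrophils is argued against, since the 25 macrophage genes exceeded the 21 tumour, fibroblast, endothelial, T and NK genes with a mean of 10 CPM or more, of 45 tested, by 1.22 in mean log2 fold change (medians over all tested members -0.40 for tumour, -0.33 for fibroblast and endothelial and 0.22 for T and NK genes, permutation p = 1e-05, two-sided, the smallest it can give, with genes not independent). A larger share of RNA of the Ly6G-low kind is argued against as the whole cause: 88% of the 25 macrophage genes exceeded both the T1-non-binding and the Ly6G-low level in both mice (library totals), where mixing gives a level between them, and the share that the neutrophil fall needs (44.6% and 52.2%) would raise the 16 markers further than seen, with an upper quartile of observed over needed level of 0.486 in mouse 1 and 0.832 in mouse 2. Single markers reached 1.36 in mouse 1 and 1.02 in mouse 2. Macrophages or their RNA within the T1-binding gate may account for the pattern, but T1-binding Ly6G-high cells that carry these transcripts themselves predict the same. That 92% of the 25 macrophage genes were higher in both mice restates the pattern, so it favours neither. A sort on Ly6G may remove macrophages, but its purity is not stated, and both Ly6G-high gates held macrophage transcripts (Mrc1 at 202 to 780 CPM). These explanations were not told apart.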
